A study of Danio rerio with 8 samples.

How the data were processed

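RNA was extracted with Trizol from sorted EGFP-positive cells without pigment, and libraries were prepared with Illumina TruSeq chemistry, per the labels' protocols. The deposited table of counts holds whole numbers of reads per gene for 28272 Ensembl gene identifiers in 8 columns, made by the authors. A deposited table of normalized signal holds the same counts divided by 1 size factor per library, a ratio that was constant within each library. The submitters' processing notes name STAR 2.3, HTSeq and DESeq2 and the genome build Zv9, with no role or order. The annotation release, strand setting and treatment of multiply aligned reads are not given in the sources used here, so overlapping genes and near-identical copies can share or lose reads. The smallest row sum was 40 counts and the smallest highest count of a row 12, so low genes had been left out before deposit.

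Columns were matched to samples by name. Both remaining melanocytes columns carry the name of replicate 3, so they were used as members of the melanocytes group without a replicate number and are called its first and second column. No column of per-sample values was left unused. No pair of libraries agreed within counting noise: the smallest chi-square per degree of freedom was 139. Symbols were found for 19599 of 28272 identifiers, and these held between 80.9% and 87.2% of counts; 2765 identifiers share a symbol with another. Neighbouring genes were taken from the RefSeq annotation of assembly GRCz12tu, which is not the authors' build, so no coordinates are given. A genome of the authors' build was not used here.

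Genes were kept by filterByExpr and tested with edgeR 4.0.16 (TMM, quasi-likelihood, group as the only term) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists with at least 5 measured members were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, with an estimated correlation, and with fry, whose directional p does not compare a list with other genes. The 26 lists, the tests and the rule for named genes were fixed before the data were examined. Of 739 listed symbols 625 were matched to a row: 470 rows by symbol, 168 without the paralog letter and 7 by synonym. Named genes were slc45a2, braf, mitfa, gdf6a and gdf6b; the 10 largest rises and 10 largest falls among called genes with no overlap between groups, a mean of at least 10 CPM and a proper, unique symbol; and up to 2 risen and 2 fallen members per list by adjusted p. Genes outside this rule are marked as chosen after their values were seen. Some genes that this rule names, and 1 of the lists, are not reported here. Principal components used log2 CPM with a prior count of 2.

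Depths of 86888494 to 100270657 counts per library left counting error small for genes above 1 CPM. TMM factors ranged from 0.467 to 1.67. On simulated counts for this comparison, run over 26749 genes, the test recovered 0% of 50 genes changed 2-fold, 12% of those changed 4-fold, 74% of those changed 16-fold and 90% of those changed 64-fold, with 1 false call among 89. A planted list was called and 0 null lists were. Genes were simulated independently of each other, so the null lists cannot show how camera behaves with correlated genes. With so few genes changed, the adjusted threshold was stricter there than in the real comparison, so these shares do not measure its recovery.

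Alternatives were DESeq2 1.42.0, RLE and upper quartile scaling, limma-voom, no filter, a filter of 5 CPM in 4 libraries, an adjusted p of 0.01, a 2-fold minimum, the replicate number as a block, and leaving out each library. Chosen after seeing the data were total counts alone, the authors' size factors, and leaving out the 2 melanocytes libraries with the fewest genes at 10 counts (replicate 2 and the second column of replicate 3), called the 2 less complex libraries. The same tests were run on 4 lists compiled once the data had been examined (cholesterol synthesis, proteasome, ribosomal proteins and chaperones), adjusted over these 4. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for tables and figures.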

Results

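Gene counts were taken from 8 RNA-seq libraries of adult zebrafish that carry human BRAF with the V600E change under the mitfa promoter, EGFP under the mitfa promoter and a mutation at the alb locus. EGFP-positive cells without pigment had been isolated by cell sorting, 4 libraries from cells the labels call scale melanocytes and 4 from melanomas. The study's question was how gene expression differs between these cell types. Each library held between 86888494 and 100270657 counts over 28272 genes. The first set is called the scale libraries here, because several of its transcripts go against the cell type on the label, as given below. Differences between the sets, for any gene or list below, therefore cannot be separated from a difference in the kinds of cells they held. Levels are TMM-normalized CPM (read counts scaled to a common library size), mean ± SD over n = 4 libraries per group. Changes are log2 fold changes ± SE, melanoma against scale libraries, from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. That test gives no SE, so the size of the change divided by the square root of its F statistic was used. This SE is approximate, above all for genes with few counts in either group. The labels do not say whether libraries came from separate fish, so p-values measure the spread between these libraries, which may be technical.

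The libraries fell apart by the group on their label. On the 1000 most variable genes the first principal component held 86.4% of the variance, with the 4 scale libraries between -117 and -83.1 and the 4 melanoma libraries between 76.5 and 124. Correlations across these genes, which are not independent replicates, were 0.884 to 0.944 within scale libraries, 0.726 to 0.877 within melanoma and -0.282 to 0.0806 between groups. Genes chosen for their variance favour those that differ between the groups. Over all 26749 tested genes the first component held 57.8% of the variance. There correlations were 0.852 to 0.950 within scale libraries, 0.888 to 0.942 within melanoma and 0.650 to 0.735 between groups (mean 0.693). On the 1000 genes melanoma replicate 1 had the lowest position of its group on both leading components. Scale libraries were dominated by few transcripts: their 10 most counted genes took between 31.9% and 41.6% of counts, against 5.83% to 6.51% in melanoma. Genes with at least 10 counts numbered 26377, 22836, 26448 and 22537 in scale replicate 1, replicate 2 and the first and second column of replicate 3, and between 24832 and 26706 in melanoma.

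**Figure D1:**
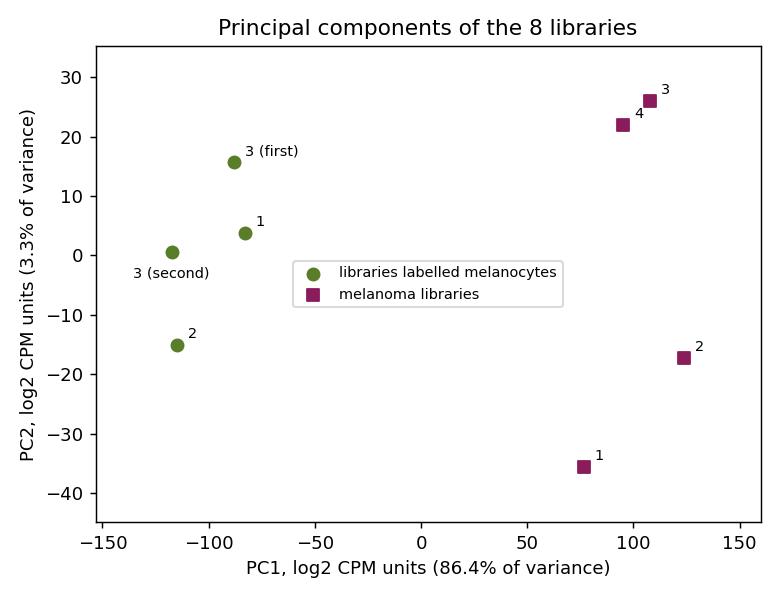
Principal components of log2 CPM over the 1000 most variable genes, 1 point per library (circles, libraries labelled melanocytes; squares, melanoma), with replicate numbers beside the points. The groups lie apart on the first component, from -117 to -83.1 and from 76.5 to 124, and melanoma replicate 1 lies lowest on the second.

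Of the 26749 genes, 5799 were higher and 4056 lower in melanoma at an adjusted p under 0.05. The groups did not overlap for 9858 genes, where chance gives 2.86%. Among called genes 58.8% were higher in melanoma. With RLE size factors 5058 genes were higher and 4477 lower, and with the authors' size factors 53.4% of calls were higher. Upper quartile scaling gave 41.6% (4041 higher, 5667 lower) and total counts alone 85.9% (10873 higher, 1778 lower), so the balance of directions depended on the scaling. Without the 2 less complex scale libraries, defined with the methods as replicate 2 and the second column of replicate 3, 5000 genes were higher and 5006 lower. Without melanoma replicate 1, 5822 were higher and 3964 lower. The median log2 change of all genes was 0.05 as reported, -0.06 with RLE, -0.39 with upper quartile and 1.17 with total counts, and the changes below stand relative to it.

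The genes that rose most in melanoma included regulators of the neural crest, the embryonic source of pigment cells. The crest transcription factor sox10 (ENSDARG00000077467) was at 0.724 ± 0.355 CPM in the scale libraries and 302 ± 116 CPM in melanoma (log2 change 8.71 ± 0.59, adjusted p = 9.21e-06). The crest factor foxd3 (ENSDARG00000021032) was at 0.254 ± 0.110 against 72.7 ± 32.1 CPM (log2 change 8.14 ± 0.58, adjusted p = 9.21e-06). The melanin synthesis enzyme dct (ENSDARG00000006008) rose from 2.65 ± 1.07 to 542 ± 448 CPM (log2 change 7.68 ± 0.85, adjusted p = 6.39e-05). Also among the 10 largest rises were the homeobox genes hoxd9 (log2 change 8.39) and hoxd10 (8.03), the connexin gja4 (7.44), the thymosin gene tmsb2 (7.31), kctd4 (10.53), the muscle ubiquitin ligase trim63a (10.15) and the apolipoprotein gene apoda.1 (7.88). Several of these rested in part on 1 library: without melanoma replicate 3 the changes were 9.25 for kctd4, 5.46 for apoda.1 and 7.47 for hoxd9, and without melanoma replicate 1 that of trim63a was 7.15. Without the first column of scale replicate 3, trim63a stood at 10.85 and hoxd10 at 8.77, and without scale replicate 2 tmsb2 stood at 8.10. The call of kctd4 was lost with limma-voom (adjusted p = 0.189), and without the 2 less complex scale libraries hoxd10 stood at 7.14 and kctd4 at 9.92.

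The genes that fell most were those of epidermis, mineralized scale and lipid metabolism. Keratins krt91 (ENSDARG00000036830) and krt97 (ENSDARG00000000212) were among them. The first was at 28773 ± 15064 CPM in the scale libraries (log2 change -11.42 ± 1.33, adjusted p = 8.65e-05), and the second at 7487 ± 3003 against 2.48 ± 2.90 CPM (log2 change -11.56 ± 1.88, adjusted p = 0.000627). The enamelin gene enam (ENSDARG00000092730), for a matrix protein of mineralized tissue, was at 91.4 ± 106 against 0.0121 ± 0.0242 CPM (log2 change -12.75 ± 1.56, adjusted p = 0.000117). The gene scpp7, for a secretory calcium-binding phosphoprotein, fell by 11.06 on the log2 scale. Each of enam and scpp7 had only 7 counts over the 4 melanoma libraries, so the fitted sizes of their falls depend on the prior count. The prostaglandin D synthase genes ptgdsb.1 and ptgdsb.2, whose similar sequences may share reads, changed by -11.75 and -12.15. Sterol genes followed: cyp7a1 (log2 change -11.10), which encodes the rate-limiting enzyme of bile acid synthesis, ch25hl1.1 (-11.04), a cholesterol 25-hydroxylase-like gene, and msmo1 (-10.82), of cholesterol synthesis. Leaving out melanoma replicate 1 moved ptgdsb.1 to -13.15, ptgdsb.2 to -12.82, krt97 to -12.40 and cyp7a1 to -12.40. Leaving out melanoma replicate 4 moved enam to -16.12, scpp7 to -12.23 and krt91 to -12.35. Without scale replicate 1 enam stood at -13.37 and scpp7 at -11.71, without scale replicate 2 at -13.37 and -11.65, and without the second column of scale replicate 3 at -11.71 and -9.84.

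The gene at the alb locus, slc45a2 (ENSDARG00000002593), a melanosome transporter, was at 4.92 ± 1.38 CPM in the scale libraries and 95.0 ± 37.7 CPM in melanoma (log2 change 4.27 ± 0.45, adjusted p = 4.45e-05). Another gene, gdf6a (ENSDARG00000053479), encodes a BMP ligand. It was at 0.352 ± 0.198 CPM in the scale libraries and 51.3 ± 10.3 CPM in melanoma (log2 change 7.18 ± 0.54, adjusted p = 9.21e-06). Each of the 4 melanoma libraries lay above every scale library, but the groups did not overlap for 9858 of the 26749 tested genes. The paralog gdf6b lay near the floor, at 0.305 ± 0.323 against 0.132 ± 0.176 CPM (adjusted p = 0.522). Zebrafish braf did not pass (log2 change 0.28 ± 0.68, adjusted p = 0.771), and its direction turned under upper quartile scaling (-0.20) and without the second column of scale replicate 3 (-0.17) or both less complex scale libraries (-0.37). No row is named mitfa. Of the 2 rows named mitf, the pigment cell master regulator, ENSDARG00000003732 rose by 2.55 ± 0.75 (adjusted p = 0.0193). The other, ENSDARG00000037833 was at 2.87 ± 0.993 against 1.71 ± 0.874 CPM (adjusted p = 0.301), with its sign turned under total counts (0.33). The call of the first was lost without scale replicate 2 (0.0506) or the first column of scale replicate 3 (0.0507) and with the 5 CPM filter (0.0591). Its change was 3.26 without scale replicate 1 and 1.81 without the 2 less complex libraries.

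Of 26 gene lists fixed before the data were examined, camera with a preset correlation of 0.01 called 5 higher and 3 lower. None of the 8 kept its call with an estimated correlation, so that p is given beside each.

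Pigment cell differentiation genes rose: 17 of 26 measured members were higher and 1 lower (camera adjusted p = 0.000135, adjusted p = 0.354 with an estimated correlation; adjusted over the list alone, 17 were higher and 1 lower). They took 0.0202% ± 0.00476 of counts in the scale libraries and 1.02% ± 0.604 in melanoma. The melanosome receptor gpr143 was at 4.02 ± 0.633 against 398 ± 196 CPM (log2 change 6.63 ± 0.54, adjusted p = 1.2e-05). The melanosome fibril gene pmela was at 22.5 ± 11.9 against 1981 ± 1318 CPM (log2 change 6.46 ± 0.69, adjusted p = 5.11e-05). The copper transporter atp7a fell by 2.32. Chosen after their values were seen, the tyrosinase gene tyr was at 1.28 ± 0.709 against 38.6 ± 12.8 CPM, the melanocortin receptor mc1r at 0.189 ± 0.140 against 17.7 ± 10.9 CPM, and the receptor tyrosine kinase kit at 15.9 ± 4.87 against 81.1 ± 11.7 CPM. These 3 rose (adjusted p = 6.08e-05, 0.000175 and 0.000362). Of 2 rows named tyrp1, ENSDARG00000056151 was at 35.7 ± 12.9 against 2929 ± 2525 CPM (adjusted p = 0.000253). The tyrp1 change was 5.69 without melanoma replicate 3, against 6.36. The melanosome channel gene oca2, chosen likewise, did not pass (log2 change -0.89 ± 0.55, adjusted p = 0.221). It was called lower with the 5 CPM filter (adjusted p = 0.0367) and without the 2 less complex libraries (0.0311), and its sign turned under total counts (0.0222). Iridophore markers, genes of the reflective pigment cells, had 10 of 19 members higher and 0 lower (camera adjusted p = 0.00365, adjusted p = 0.427 with an estimated correlation; adjusted over the list alone, 10 were higher and 0 lower). They included the endothelin receptor ednrb (6.05) and the purine enzyme pnp4a (5.73, and 4.87 without melanoma replicate 3). The pigment cell list holds ednrb too, so these lists are not fully separate. Neural crest genes moved both ways, 10 of 28 up and 10 down (camera adjusted p = 0.986; adjusted over the list alone, 10 were higher and 10 lower), and the list's median of -0.59, its mean of 0.11, camera (down) and fry (up) differed in sign. The homeobox genes msx1b (-8.66) and msx3 (-3.35) fell while sox10 and foxd3 rose. Of 11 xanthophore markers, 1 rose, the sugar transporter gene slc2a15b (4.98), and 1 fell, akr1b1 (-3.65; camera adjusted p = 0.802; adjusted over the list alone, 1 were higher and 1 lower). The median was 0.16 but the mean -0.03 and camera's direction down. Under total counts 5 rose and 1 fell, and with upper quartile scaling or without the second column of scale replicate 3, 1 rose and 3 fell. Without scale replicate 1, 2 rose and 1 fell, and without scale replicate 2, 1 rose and 2 fell.

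**Figure D2:**
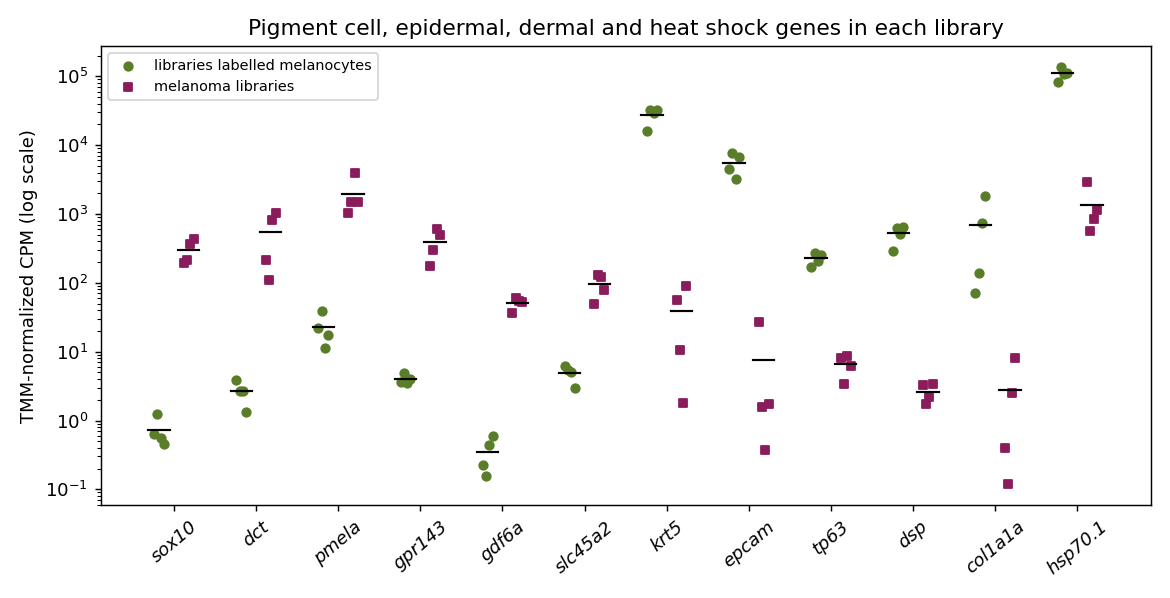
TMM-normalized CPM on a log axis for 12 genes in each library (circles, libraries labelled melanocytes; squares, melanoma; bars, means of n = 4). The crest factor sox10, the BMP ligand gene gdf6a and the pigment genes dct, pmela, gpr143 and slc45a2 lie higher in all 4 melanoma libraries. The genes krt5, epcam, tp63, dsp, col1a1a and hsp70.1 lie higher in all 4 libraries labelled melanocytes.

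Epidermal genes fell: 30 of 32 members were lower in melanoma and 0 higher (camera adjusted p = 3.52e-23, adjusted p = 0.354 with an estimated correlation; adjusted over the list alone, 0 were higher and 30 lower), with a median log2 change of -6.68. In the scale libraries the mean log2 level of the list was between 7.72 and 8.82, and in melanoma between 1.41 and 2.81. The desmosome gene dsp was at 521 ± 164 against 2.61 ± 0.800 CPM (log2 change -7.64 ± 0.53, adjusted p = 9.21e-06). The epidermal gene icn2 was at 1485 ± 773 against 2.34 ± 0.903 CPM (log2 change -9.31 ± 0.70, adjusted p = 9.22e-06). Named after their values were seen, krt5 was at 27604 ± 7720.1 against 39.3 ± 40.7 CPM (adjusted p = 0.000239). The epithelial adhesion gene epcam, chosen likewise, was at 5568 ± 2044 against 7.56 ± 12.7 CPM (adjusted p = 0.000456), and the epidermal transcription factor tp63 at 227 ± 47.6 against 6.52 ± 2.35 CPM (adjusted p = 1.75e-05). Changes grew to -10.24 for krt5 without melanoma replicate 4 and to -12.13 for epcam without melanoma replicate 1. Fibroblast and scale bone genes fell likewise, 23 of 27 lower and 0 higher (camera adjusted p = 4.9e-10, adjusted p = 0.354 with an estimated correlation; adjusted over the list alone, 0 were higher and 23 lower). Osteocalcin, bglap, changed by -8.47 and the chemokine cxcl12 by -5.31, and bglap stood at -7.53 without the second column of scale replicate 3 and -9.07 without scale replicate 1. Collagen col1a1a, named after its values were seen, was at 689 ± 806 against 2.81 ± 3.74 CPM and varied between 71.3 and 1813 CPM among scale libraries. Its log2 change was -7.94, and -9.39 without melanoma replicate 4, -6.90 without the second column of scale replicate 3, -8.60 without scale replicate 1 and -8.56 without scale replicate 2.

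Immediate early and heat shock genes on the list of dissociation stress fell, 17 of 25 lower and 1 higher (camera adjusted p = 1.99e-10, adjusted p = 0.354 with an estimated correlation; adjusted over the list alone, 1 were higher and 19 lower). The list took 12.4% ± 2.36 of counts in the scale libraries and 0.867% ± 0.578 in melanoma. The cochaperone dnajb1b was at 6486 ± 1975 against 96.0 ± 12.5 CPM (log2 change -6.08 ± 0.56, adjusted p = 2.16e-05), and the transcription factor klf2a changed by -5.19. By contrast socs3, a cytokine signalling inhibitor, rose by 1.98. That rise was not called without scale replicate 1 (adjusted p = 0.0746), scale replicate 2 (0.0517) or the first column of scale replicate 3 (0.0709), nor without the 2 less complex libraries (0.0537) or with the replicate number as a block and the columns of replicate 3 exchanged (0.0614), and stood at 1.13 without melanoma replicate 1. The heat shock gene hsp70.1, chosen after its values were seen, was at 109830 ± 22113 CPM in the scale libraries and 1366 ± 1036 CPM in melanoma (log2 change -6.33 ± 0.88, adjusted p = 0.000246; -6.99 without melanoma replicate 1). Its near-identical copies may exchange reads.

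Cell cycle genes rose, 39 of 44 higher and 1 lower (camera adjusted p = 2.62e-09, adjusted p = 0.481 with an estimated correlation; adjusted over the list alone, 40 were higher and 1 lower). The list took 0.0209% ± 0.00325 of counts in the scale libraries and 0.319% ± 0.207 in melanoma, and its mean log2 level was 2.94 in melanoma replicate 1 against 4.68 to 5.72 in the other melanoma libraries. The spindle genes tpx2 (1.64 ± 0.857 against 64.2 ± 39.5 CPM; log2 change 5.28 ± 0.64, adjusted p = 0.000115) and prc1 (log2 change 5.11) rose, and cdc6, which licenses replication origins, fell by 2.01, a call lost under total counts (adjusted p = 0.131). Chosen after their values were seen, cdk1 rose by 4.80, top2a by 4.19 (3.32 without melanoma replicate 3) and mki67 by 3.28, a call lost with the replicate number as a block (adjusted p = 0.0846). Ribosome biogenesis genes rose, 23 of 25 higher and 0 lower (camera adjusted p = 9.21e-11, adjusted p = 0.354 with an estimated correlation; adjusted over the list alone, 23 were higher and 0 lower), among them ebna1bp2 (2.67) and wdr3 (3.58). Chromatin repressors rose, 13 of 17 higher and 0 lower (camera adjusted p = 3.27e-05, adjusted p = 0.354 with an estimated correlation; adjusted over the list alone, 13 were higher and 0 lower), led by the heterochromatin protein genes cbx5 (17.7 ± 6.57 against 295 ± 136 CPM) and cbx3 (41.3 ± 19.1 against 448 ± 158 CPM).

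**Figure D3:**
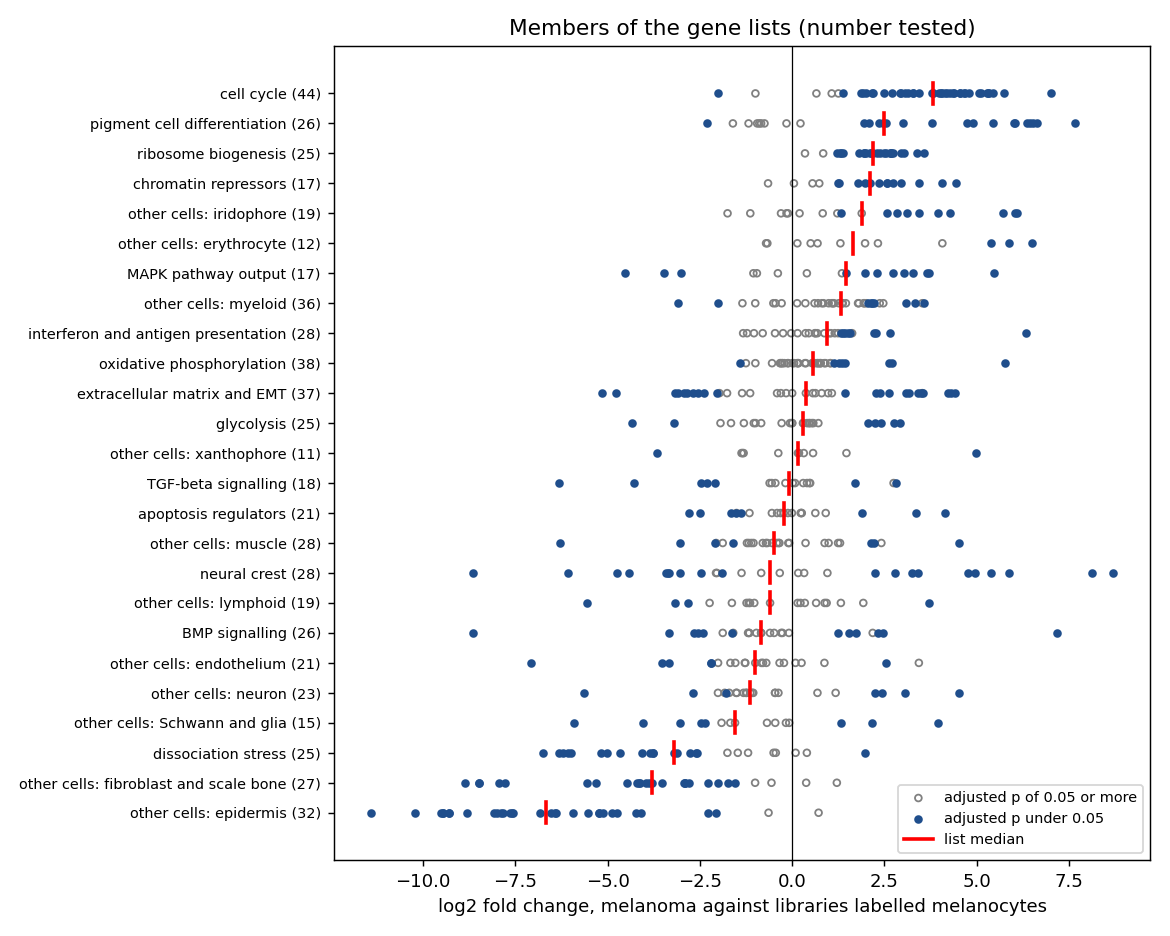
Log2 fold change, melanoma against libraries labelled melanocytes, of each tested member of 25 of the 26 gene lists (filled, adjusted p under 0.05; open, not passed; red bar, list median). The medians run from -6.68 for epidermis to 3.83 for cell cycle. With total counts alone the median of all genes is 1.17 higher than 0, and the slightly negative medians of TGF-beta signalling and apoptosis regulators turn positive.

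Outputs of the MAPK pathway, which BRAF drives, moved apart: 9 of 17 rose and 3 fell (camera adjusted p = 0.104; adjusted over the list alone, 10 were higher and 3 lower). The phosphatase gene dusp4 was at 2.51 ± 1.22 against 112 ± 15.9 CPM (log2 change 5.48 ± 0.49, adjusted p = 2e-05), and the ETS factor etv4 rose by 3.72. Another phosphatase gene, dusp5 (-4.53; -5.44 without melanoma replicate 1), and fosl1 (-3.47; -4.06 without it) fell. In BMP signalling 6 of 26 members rose and 6 fell (camera adjusted p = 0.146; adjusted over the list alone, 6 were higher and 8 lower). Risen members included gdf6a and the effector smad1 (2.33), and fallen ones msx1b and the ligand bmp2 (-3.33). Without the 2 less complex libraries 3 rose. In TGF-beta signalling 2 of 18 rose and 5 fell (camera adjusted p = 0.17; adjusted over the list alone, 2 were higher and 5 lower). Here tgfbi (2.81) and smad2 (1.70) rose, and the ligand tgfb3 (164 ± 54.3 against 2.07 ± 0.709 CPM; log2 change -6.31 ± 0.47, adjusted p = 9.21e-06) and receptor tgfbr2 (-2.48) fell. Under total counts the medians of the BMP, TGF-beta and neural crest lists turned positive (0.41, 1.12 and 0.61). There 8 BMP members rose and 2 fell, against 5 and 10 with upper quartile scaling, and 5 TGF-beta members rose and 3 fell. Fry, which does not compare a list with other genes, called the MAPK list higher (adjusted p = 0.00255). It called the BMP and TGF-beta lists lower (adjusted p = 0.000474 and 0.00221).

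Matrix and mesenchymal genes had 12 of 37 members up and 10 down (camera adjusted p = 0.967; adjusted over the list alone, 12 were higher and 11 lower). The transcription factor zeb2a (19.2 ± 10.2 against 415 ± 102 CPM; log2 change 4.43 ± 0.51, adjusted p = 8.16e-05) and integrin itga5 (3.17) rose, and itgb3 (-5.14; -6.66 without melanoma replicate 1) and col18a1a (-2.55) fell. In glycolysis 5 of 25 rose and 2 fell (camera adjusted p = 0.802; adjusted over the list alone, 5 were higher and 2 lower). The enzymes aldoc (2.24) and eno1 (2.75) were up, and the glucose carrier slc2a1 (-3.20) and lactate carrier slc16a3 (-4.33; -6.09 without melanoma replicate 1) were down. Medians of both lists turned negative with upper quartile scaling (-0.08 and -0.15). Under total counts 17 matrix genes rose and 3 fell, and 14 glycolysis genes rose and 2 fell. Oxidative phosphorylation had 7 of 38 up and 1 down (camera adjusted p = 0.104; adjusted over the list alone, 4 were higher and 0 lower). There ndufa4b (5.78; 6.44 without scale replicate 1) and sdhd (2.71) rose, and cox5aa fell by 1.40, a call lost in 6 of the 8 fits that left out 1 library (adjusted p from 0.0514 to 0.0936 in those 6) and with the replicate number as a block (0.0793). The cox5aa change shrank to -0.48 without the 2 less complex libraries (adjusted p = 0.343) and to -0.07 under total counts (0.885). The sdhd call was lost with limma-voom (adjusted p = 0.101) and with the block when the columns of scale replicate 3 were exchanged (0.0650), and also without the 2 less complex libraries (0.0711). The number of risen members was 2 without scale replicate 1, 3 without scale replicate 2 or the first column of replicate 3, 4 without melanoma replicate 2 or 3, 15 without the 2 less complex libraries and 35 under total counts. With RLE or the authors' size factors 3 rose and 1 fell, with DESeq2 5 rose and 3 fell, with upper quartile scaling 3 rose and 3 fell, and with the 5 CPM filter 0 rose and 4 fell.

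Interferon and antigen presentation genes had 9 of 28 up and 0 down (camera adjusted p = 0.104; adjusted over the list alone, 9 were higher and 0 lower). These counts moved with scaling and filter: 4 up and 3 down with upper quartile scaling, 8 and 2 with DESeq2, 6 and 0 with RLE, 2 and 2 with the 5 CPM filter, and 22 and 0 under total counts. Their smallest adjusted p values belonged to ifit10 (log2 change 6.34) and irf9 (1.44). The number up was 3 without scale replicate 1 or 2 and 2 without the first column of scale replicate 3, and irf9 lost its call in each of these fits (adjusted p = 0.0705, 0.0564 and 0.0726) and with the 5 CPM filter (0.0510). Apoptosis regulators had 3 of 21 up, among them bcl2a (3.36) and birc5 (4.15; 4.76 without scale replicate 2), and 5 down, among them mcl1a (-2.80) and bada (-1.64; camera adjusted p = 0.492; adjusted over the list alone, 3 were higher and 5 lower). The number down was 2 without melanoma replicate 3 or 4 or without the 2 less complex libraries. Under total counts the balance turned over, with 9 up and 1 down. The bada call was lost without the 2 less complex libraries (adjusted p = 0.111) and under total counts (0.463).

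Markers of blood cells differed among the melanoma libraries. Of 36 myeloid markers 7 rose and 2 fell (camera adjusted p = 0.492; adjusted over the list alone, 7 were higher and 2 lower). With the replicate number as a block 2 rose and 2 fell, with upper quartile scaling 4 rose and 2 fell, and under total counts 21 rose and 0 fell. The macrophage receptor marco (3.57; 2.55 without melanoma replicate 1) and complement c1qb (3.34; 2.41 without it) were up. The macrophage gene mpeg1 (10.3 ± 1.23 against 2.59 ± 1.04 CPM) and cebpb (log2 change -3.10) were down. The mean log2 level of the list was 6.71 in melanoma replicate 1 and 3.19 to 4.39 in the other melanoma libraries, and without that library 3 markers rose and 7 fell. Those that rose numbered 2 without scale replicate 1 or 2 and 3 without the first column of scale replicate 3. The cebpb call was lost without scale replicate 2 (adjusted p = 0.0530), melanoma replicate 2 (0.0567) or 4 (0.0523), and its change was -4.62 without melanoma replicate 1. It was also lost without the 2 less complex libraries (0.125) and under total counts (0.124), where the mpeg1 call was lost too (0.202). Of 12 erythrocyte markers 3 rose and 0 fell (camera adjusted p = 0.802; adjusted over the list alone, 3 were higher and 0 lower), and without melanoma replicate 1 none did. There cahz, a carbonic anhydrase gene, was at 375 CPM in that library and 2.31 to 4.61 in the others (adjusted p = 0.0186; 0.431 without it and 0.348 with the replicate number as a block). The unnamed marker ENSDARG00000077504 likewise lost its call (adjusted p = 0.014; 0.224 without it). With DESeq2 or limma-voom no erythrocyte marker was called. The number that rose was 1 without scale replicate 1, 2 or the first column of 3, fits in which cahz was not called (adjusted p = 0.0652, 0.0593 and 0.0569), and 0 without the 2 less complex libraries. Of 19 lymphoid markers cd28 (3.71; 4.49 without the second column of scale replicate 3) rose and 3 fell, cd8a (-5.55) and cd8b (-2.83) among them (camera adjusted p = 0.442; adjusted over the list alone, 1 were higher and 2 lower). The number that fell was 5 with DESeq2 or without the 2 less complex libraries, 2 without scale replicate 1, scale replicate 2, the first column of scale replicate 3 or melanoma replicate 3, and 1 under total counts, where 2 rose. The cd8b call was lost under total counts (-1.58, adjusted p = 0.112).

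Markers of the remaining cell types moved both ways. Endothelial markers had 1 of 21 up, the receptor tek (2.56), and 5 down (camera adjusted p = 0.146; adjusted over the list alone, 1 were higher and 4 lower; 2 down without melanoma replicate 4, 3 with the replicate number as a block and 1 under total counts). The falls included sox7 (165 ± 67.6 against 1.21 ± 0.198 CPM; log2 change -7.09 ± 0.46, adjusted p = 9.21e-06) and sox18 (-3.53; adjusted p = 0.0701 under total counts). Schwann cell and glial markers had 3 of 15 up and 5 down (camera adjusted p = 0.0988; adjusted over the list alone, 3 were higher and 5 lower). Of these cnp (1.33) and sox2 (3.96) rose, and erbb3b (-3.03) and erbb3 (-2.37) fell. Fry called this list lower (adjusted p = 0.000474). The number up was 0 with upper quartile scaling or the 5 CPM filter, 0 without scale replicate 1, 0 without the second column of scale replicate 3 and 1 without the first, or without melanoma replicate 3. The calls of cnp were lost without scale replicate 1 (adjusted p = 0.0966) or either column of replicate 3 (0.0944 and 0.0537), and those of sox2 in 6 of 8 such fits (0.0510 to 0.0965), with a change of 7.73 without scale replicate 2. With upper quartile scaling neither was called (0.0652 and 0.0575), nor cnp with the 5 CPM filter (0.0639) or sox2 with DESeq2 (0.0618). Of 23 neuronal markers 4 rose and 3 fell (camera adjusted p = 0.492; adjusted over the list alone, 4 were higher and 3 lower; 6 fell without the second column of scale replicate 3). They included tubb5 (3.06) and vamp2 (4.53), which rose. The neurofilament gene ina (-5.64; -6.64 without melanoma replicate 2; -4.91 without the second column of scale replicate 3) and stmn2 (-1.78; adjusted p = 0.0565 without melanoma replicate 3 and 0.0504 with the replicate number as a block and the columns of replicate 3 exchanged) fell. The number of neuronal markers that fell was 7 with DESeq2 or upper quartile scaling and 10 without the 2 less complex libraries. It was 2 without scale replicate 1, the first column of scale replicate 3 or melanoma replicate 2, 3 or 4, and 1 under total counts. The stmn2 call was lost under total counts, where its change was -0.62 (adjusted p = 0.455). Muscle markers had 3 of 28 up and 4 down (camera adjusted p = 0.492; adjusted over the list alone, 3 were higher and 2 lower; 2 down without scale replicate 1 or melanoma replicate 1, 2 or 3; 7 down without the 2 less complex libraries; 5 up and 1 down under total counts). Higher were casq1 (2.22) and myl1 (2.14), and tnnt3 (-3.05; adjusted p = 0.0519 under total counts) was lower. The calcium pump gene atp2a1 was at 143950 ± 29156 against 1831 ± 1363 CPM (log2 change -6.30 ± 0.90, adjusted p = 0.000286; -6.94 without melanoma replicate 1). The atp2a1 value is uncertain, since its count kept a ratio of 1.31 to 1.37 to that of hsp70.1 in all 8 libraries.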

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

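All tests of explanations in this part, and the splits of the libraries, were chosen after the results were seen. A gap of 1 library to the rest of its group was examined in 290 groups of 4 values. Of these, 15 gaps exceeded Dixon's 95% limit, where chance passes about 5%. That number is close to what chance gives, so the gaps are only described. Melanoma replicate 1 accounted for 4. There cahz stood at 375 CPM (2.31 to 4.61 in the other melanoma libraries), the erythrocyte marker ENSDARG00000077504 at 26.1 (0.197 to 0.484), the mean log2 level of the erythrocyte list at 4.26 (0.346 to 0.951) and slc2a15b at 37.2 CPM (112 to 121). Scale replicate 2 accounted for 6, with sox7 at 267 CPM (128 to 134 in the other scale libraries), eno1 at 4.53 (2.40 to 2.64), birc5 at 2.18 (0.503 to 0.598), bcl2a at 0.978 (0.560 to 0.566), sox2 at 0.622 (0 to 0.0267) and myl1 at 2.0 (4.87 to 4.92). The keratin krt5 was at 16240 CPM in scale replicate 1 (29320 to 32580 in the others), cd8a at 3.82 in the first column of scale replicate 3 (1.32 to 1.45), and the mean log2 level of chromatin repressors at 2.83 in its second column (3.10 to 3.13). In melanoma, enam was at 0.0484 CPM in replicate 4 (0 in the others) and tnnt3 at 0.0867 in replicate 2 (0.670 to 0.744).

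Scale libraries held few pigment cell transcripts: the pigment cell list took 0.0202% of their counts and 1.02% in melanoma, and sox10 reached at most 1.24 CPM there. A swap of some labels between the groups is argued against, since the lowest mean log2 level of that list in melanoma was 1.64 above the highest in scale libraries, so no melanoma library was out of place. The 2 less complex libraries are not the whole source, since without them the median log2 change of the list was 2.43. Epidermal and other scale cells in the sorted fraction may be a candidate explanation, since the epidermal list, fixed before the data were examined, had a median change of -6.68 with krt5, krt91 and epcam among abundant transcripts, though a sort for EGFP would be meant to remove such cells. Low levels of lineage transcripts in scale melanocytes alone would not account for the transcripts of other cell types. The mean log2 level of the epidermal list was 7.72 to 8.82 in scale libraries and 1.41 to 2.81 in melanoma. Of the fibroblast and scale bone list, 23 of 27 members were lower in melanoma and 0 higher. For these 2 lists the values argue against scale melanocytes as the only cells. Whether melanocytes within such a mixture had low levels of lineage transcripts cannot be told, because their share is not known. A difference between melanocytes and melanoma cells stays open only to that extent.

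The most counted gene of the scale libraries was atp2a1, with 9.50% ± 2.02 of counts, against 0.290% ± 0.239 in melanoma. Muscle cells are argued against: the other 27 muscle rows together took 0.00342% of counts in scale libraries. Reads of the neighbouring hsp70 genes counted as atp2a1 are a candidate explanation. The log2 ratio of atp2a1 to hsp70.1 counts had an SD of 0.0258 over the 8 libraries, while that of the atp2a1 share was 2.95, and hsp70.1, hsp70.2 and hsp70.3 precede atp2a1 in assembly GRCz12tu. No other biological explanation was tested.

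Scale replicate 2 and the second column of scale replicate 3 had 22836 and 22537 genes with at least 10 counts, against 26377 and 26448 in the others. A lower total count is argued against, since scale replicate 2 had the highest total of its group (96320824 counts). A larger share of the 10 most counted genes is argued against too, since these took at most 33.9% in this pair and at least 36.1% in the others. That test cannot decide on a wider set of abundant genes. TMM factors were 0.467 and 0.538 in this pair, against 0.863 and 0.874 in the other scale libraries, so a wider set stays open. Fewer RNA molecules at the start of the library cannot be told apart from other causes without molecular identifiers: 348 genes, 1.35% of those with at least 10 counts in both others, were at 0 in both. No biological explanation was tested, since the labels give none.

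Among the 35 splits of the 8 libraries into 4 and 4, only the real one gave as many as 9855 genes, and the highest of the others gave 0. The other splits mix the groups, which raises the spread within each side, so their 0 calls add little. The share of 1 of 35 is the smallest these splits can give. It argues against chance for the number of genes but does not exclude it. For the number of lists chance cannot be excluded: 26 of the 35 splits gave at least the 8 lists of the real one, and the highest of the others gave 15. Splits with 3 libraries of 1 group on a side carry part of the real difference. Of the 18 splits with 2 libraries of each group on either side, 9 gave at least 8 lists and the highest gave 12. This concerns how many lists were called, not the separation of any single list.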

How the results depend on the processing

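No gene called higher or lower in the main comparison was called in the opposite direction under any alternative. Of 119 named genes 115 were called, 95 of them under every one of 19 alternatives that tested them. Most were named because they had passed the adjusted p threshold, so these numbers do not describe genes at large. Total counts alone, the authors' size factors and the fit without the 2 less complex libraries were chosen after seeing the data. Genes higher in melanoma numbered 5799, and 3565 at an adjusted p under 0.01, 3272 with at least 5 CPM in 4 libraries (fewer genes tested), 10873 with total counts alone, and 3981 to 5822 with 1 library left out. Genes lower numbered 4056, and 2412 at an adjusted p under 0.01, 1778 with total counts alone, and 3188 to 4653 with 1 library left out. Lists higher numbered 5, and 8 without the 2 less complex libraries, 0 with an estimated correlation and 5 to 8 with 1 library left out, highest without the second column of scale replicate 3. Lists lower numbered 3, and 5 without the 2 less complex libraries, 0 with an estimated correlation, 6 with fry and 3 to 5 with 1 library left out, highest without scale replicate 2. The 8 called lists lost their calls with an estimated correlation and kept them in the other alternatives run for lists. DESeq2, upper quartile scaling, the 5 CPM filter and the stricter adjusted p were not run for lists. The mean correlation between groups was -0.139 on the 1000 most variable genes and 0.693 on all genes. Signs turned, for genes not called, under total counts for oca2 (0.0222), mitf ENSDARG00000037833 (0.33) and gdf6b (0.0238), and for braf under upper quartile scaling (-0.20), without the second column of scale replicate 3 (-0.17) and without the 2 less complex libraries (-0.37). The cause was not tested.

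Replicate numbers did not pair the libraries: deviations from group means correlated at -0.0186 for number 1 and 0.107 for number 2. With melanoma replicate 3 they correlated at 0.172 for the first column of scale replicate 3 and -0.152 for the second, and with melanoma replicate 4 at 0.0645 and -0.0325. Pairs with unlike numbers ran from -0.147 to 0.158. With the number as a replicate block, 5049 genes were higher and 3596 lower, or 4864 and 3307 with the columns of replicate 3 exchanged, and 3 named genes lost their calls both ways: mki67 (adjusted p = 0.0846 and 0.114), cox5aa (0.0793 and 0.0519) and cahz (0.348 and 0.365). With the columns exchanged sdhd (0.0650), socs3 (0.0614), the erythrocyte marker ENSDARG00000077504 (0.0582) and stmn2 (0.0504) lost theirs too. Myeloid markers called higher numbered 2 in both of these fits, against 7. In simulated counts 12% of the genes changed 4-fold were recovered, at a stricter adjusted threshold than in the real comparison. That share does not measure recovery in the real comparison.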

Other observations

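The 4 gene lists in this part, and their tests, were chosen after the results were seen. Genes of cholesterol synthesis were lower in melanoma, 18 of 19 members, with a median log2 change of -6.09 (camera adjusted p = 3.44e-19, adjusted p = 0.0757 with an estimated correlation). The list took 0.775% ± 0.0987 of counts in the scale libraries and 0.0235% ± 0.00621 in melanoma. The C4-methylsterol oxidase gene msmo1 was at 2651 ± 1246 against 1.47 ± 0.798 CPM, cyp51a1, which demethylates lanosterol, at 2412 ± 777 against 14.5 ± 7.55 CPM and the dehydrogenase gene hsd17b7 at 1781 ± 584 against 9.21 ± 2.08 CPM. The LDL receptor gene ldlra was at 254 ± 106 against 0.181 ± 0.130 CPM (log2 change -10.45 ± 0.76, adjusted p = 9.21e-06). The number called was 17 under total counts and 18 under the other scalings. These 18 calls go with lower levels of cholesterol synthesis genes in melanoma as a group. The difference between groups has the same direction as that of the epidermal transcripts of the scale libraries. These data cannot separate the 2 differences.

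Proteasome genes were higher in melanoma, 20 of 29 members and none lower (camera adjusted p = 6.72e-09, adjusted p = 0.407 with an estimated correlation), with psma2 at 15.7 ± 6.53 against 148 ± 48.6 CPM and psmb7 at 26.4 ± 11.6 against 199 ± 80.5 CPM. The number called was 16 with RLE or upper quartile scaling, 29 with total counts, and 13 without scale replicate 1 or the first column of scale replicate 3. It was 28 without the 2 less complex libraries. A joint rise is consistent with the 20 calls, though 13 of 29 passed at the lowest, and these data cannot separate it from the epidermal transcripts of the scale libraries either.

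The hypothesis that ribosomal protein genes are lower as a group was not borne out in the main fit, where 14 of 65 were called lower, and 0 when adjusted over the list alone. Camera did call the list lower (camera adjusted p = 0.000284, adjusted p = 0.728 with an estimated correlation), and fry did not (adjusted p = 0.238). The number lower was 27 with DESeq2, 30 with upper quartile scaling and 40 of 64 with the 5 CPM filter, while 20 were higher with total counts. Without the 2 less complex libraries 0 were lower and 1 higher, with a median log2 change of 0.03. With the replicate number as a block 3 or 5 were lower. The number lower was 3 without scale replicate 2, the second column of scale replicate 3 or melanoma replicate 3 or 4, 6 without melanoma replicate 2, and 30 without the first column of scale replicate 3. Chaperone genes were likewise not lower as a group, with 9 of 29 lower and 8 higher (camera adjusted p = 0.56). The balance turned with scaling: 18 were higher and 7 lower under total counts, and 6 higher and 10 lower with upper quartile scaling. The heat-inducible hsph1 (169.5 ± 62.3 against 3.71 ± 2.29 CPM) and hsp90aa1.1 (1281 ± 476 against 79.5 ± 42.1 CPM) fell, and 1 of 2 rows of the constitutive hspa8 rose (ENSDARG00000037403; log2 change 3.62), while the other (ENSDARG00000068992) did not pass (log2 change -1.05 ± 0.51, adjusted p = 0.124). Rows of the hsp70 genes hsp70.1, hsp70.3, hsp70l and hspa2 together took 14.7% ± 3.11 of counts in scale libraries and 0.460% ± 0.397 in melanoma.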
